A study of Homo sapiens with 6 samples.

How the data were processed

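RNA was sequenced from MDA-MB-231, a human triple-negative breast cancer cell line, in 6 libraries. The labels place 3 in a control group that carried a non-targeting guide RNA and 3 in a group whose guide targeted MLL3, the histone H3 lysine 4 methyltransferase whose approved symbol is KMT2C. They number the libraries of each group as biological replicates 1 to 3. Cells were grown in DMEM with serum and left untreated, and RNA was extracted with a column kit, per the labels' protocols. The labels do not say whether the cells were clones or pools, which exon was cut, or whether the numbered guides differed in sequence.

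The submitters' processing notes name FastQC, STAR 2.4.0, featureCounts 1.5.0 and DESeq2 1.30.1, with GRCh38.p13 as the genome build. The annotation release, strand setting and filters are not given in the sources used here. The authors deposited 1 table of 15706 genes. For each library it holds a normalized read count, a signal that the authors made by dividing the reads of each gene by 1 size factor per library, and beside these stands the mean over the 6 libraries. Per the file headers it also holds the log2 fold change of knockout over control with its standard error, the Wald statistic as a score, and the authors' p-value and adjusted p-value. The authors' adjusted p-value is blank for 2337 genes, all with a mean below 24.8. The row numbers of the table run to 19211, and 3505 of them are not among the rows used here. Every row had a symbol and at least 1 read in each library, so a gene silent in any library of either group could not be tested.

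All values of a library were whole multiples of a common step, and 100% of them lay within 0.01 of a whole number after division by it. Recovered reads in the listed genes numbered 41240265, 42024652 and 48244821 in control replicates 1, 2 and 3, and 41401044, 49514464 and 48111363 in knockout replicates 1, 2 and 3. The 10 most abundant genes took between 5.63% and 6.29% of the normalized counts of a library. At this depth the spread between replicates exceeded counting error. A chi-square statistic divided by its degrees of freedom was 8.64 or more for every pair of libraries, so no library repeated another.

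Before the data were examined, the groups, the main test, 26 gene lists with 939 symbols in all, the rule for named genes and a set of alternatives were fixed. The main test was limma 3.58.1 (R 4.3.3) with a mean-variance trend on log2(value + 1), over the 14618 genes with a mean of at least 10, 3 libraries against 3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates the change of low genes. Standard errors (SE) are those of limma. A gene is called higher or lower only where its adjusted p passed the threshold. Gene lists were matched by the symbol of the file or of the same gene ID in the reference. They were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry, and adjusted over the 26 lists. With an estimated correlation camera also tests on the few residual degrees of freedom of the 6 libraries, which costs power. A call lost under that setting therefore cannot be laid to correlation between members alone. Some genes are in several lists, so calls on such lists are not independent. Camera sets the members of a list against all other genes, whereas fry asks whether the members move, on balance, in either direction. Epithelial and mesenchymal markers were compared by the difference of their median log2 fold changes, with 100000 permutations of list membership. Genes are not independent replicates in that test.

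Named genes were KMT2C, then the 10 genes with the largest increases and the 10 with the largest decreases among those past the threshold with a mean of at least 50 and no overlap between the groups. From each list up to 2 members per direction with the smallest adjusted p were added, and lists without a call are summarised mainly by their counts. Some members that met this rule are not reported here. Genes outside this rule are said to have been chosen after their values were seen.

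A trend along GC content was then found, and a further analysis was added. For each library, natural splines with 5 terms each of the GC percent and of the log2 length of the longest transcript were fitted to the gene-centred log2 values and subtracted, and the tests were repeated. This is called trend removal throughout. GC content, length and coordinates come from GENCODE 29 on GRCh38, in which 15681 of the 15706 gene IDs were found, and 14598 tested genes had both values. edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 were run on the recovered reads as further added alternatives.

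The scripts were tested on simulated data for this comparison: negative binomial counts with the means, dispersions and library sizes of the real genes, 3 libraries against 3, with 200 genes changed in each of 5 draws. Without a trend, limma recovered 64.9% of the genes changed 1.5-fold, 82.7% of those changed 2-fold and 95.9% of those changed 4-fold among 14609 genes, and 5.83% of its calls were false. With the GC and length trend of the real libraries added, limma made 2572 false calls per draw among 14605 genes. Calls on genes moved by the trend alone counted as false there, which does not tell whether the real trend is a bias. With that trend removed again limma made 9.8 false calls per draw among 14585 genes and recovered 63.5% of the genes changed 1.5-fold and 82.4% of those changed 2-fold. The added trend had the same spline form as the one removed. That result was therefore set by construction, and the simulation cannot tell whether the real trend follows this form. A list of 40 genes shifted by 0.4 (log2) was called by camera in 5 of 5 draws under each setting, and an unshifted list in 0 of 5, both at an unadjusted p. The simulated genes were drawn independently and the lists at random. The simulation therefore does not cover false list calls where the members of a list are correlated, as in the real lists.

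Alternatives covered leaving out each library, the replicate number as a block, quantile normalization, the filter on low values, the pseudocount, the thresholds, the settings of the list tests and the trend removal. Exon-level reads, splice junctions and protein were not analysed here. Figures were drawn with matplotlib 3.10.9.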

Results

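RNA-seq of MDA-MB-231 cells compared 3 control libraries with 3 libraries labelled MLL3 knockout, at 41240265 to 49514464 recovered reads per library. The title of the series asks how loss of MLL3 bears on metastasis and on a hybrid state between epithelial and mesenchymal cells. Levels below are normalized read counts, given as mean ± SD with n = 3 libraries per group. Log2 fold changes are knockout minus control with their SE and the limma adjusted p. Knockout refers to the label throughout.

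KMT2C, the targeted gene (ENSG00000055609.18, chromosome 7, 152134922 to 152436005 on GRCh38, minus strand), was read at 1334 ± 68.5 normalized counts in the control libraries and 1506 ± 161 in the knockout libraries (n = 3 each). The control libraries held 1367, 1379 and 1255 counts, and the knockout libraries 1519, 1660 and 1339. The log2 fold change of 0.17 (SE 0.10, limma adjusted p = 0.205) did not pass the threshold, and with the trend removed it was -0.039 (SE 0.071, adjusted p = 0.782). The transcript level therefore gave no check of the label, since a guide-directed cut can disrupt a protein without lowering its transcript. Among 19 measured subunits of the MLL3/MLL4 and related H3K4 methyltransferase complexes, 2 were higher and 7 lower, or 2 and 8 adjusted over the list alone. KDM6A, the H3K27 demethylase of the MLL3/MLL4 complexes, was higher by 0.36 (SE 0.096, adjusted p = 0.0094) and PSIP1 by 0.44 (SE 0.11, adjusted p = 0.0069), whereas HCFC1 fell by 0.37 (SE 0.087, adjusted p = 0.0041) and MEN1, which encodes menin, fell by 0.36 (SE 0.086, adjusted p = 0.0053). Of these, HCFC1 alone passed with the trend removed (-0.20, adjusted p = 0.033). The list then counted 0 higher and 2 lower, with 1 member called in the same direction in both analyses.

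Expression differed widely between the groups. Of 14618 genes tested, 4859 changed in limma (33.2%), 2760 higher and 2099 lower in the knockout libraries, and 147 of them changed at least 2-fold, 109 higher and 38 lower. The authors' deposited table listed 5145 genes at an adjusted p under 0.05 (2821 higher, 2324 lower), and 4782 genes were called in the same direction by both. The change followed the base composition of the transcripts. Genes in the lowest decile of GC content (30.2% to 38.7%) had a median log2 fold change of 0.44, and 63.0% of them were called higher. Genes in the highest decile (61.6% to 82.1%) had a median of -0.27, and 41.7% of them were called lower. Across genes, which are not independent replicates, Spearman's rho between fold change and GC content was -0.673. The rho between GC content and the deviation of a library from the mean of all 6, which centring sets against the other group, was 0.316, 0.459 and 0.648 in control replicates 1, 2 and 3, and -0.68, -0.589 and -0.239 in the knockout replicates. These rhos differed between the groups with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Between pairs of libraries, which need no centring, the rho was -0.711 to -0.332 for a knockout against a control library. Libraries of the same group also differed along GC content, with absolute rhos of 0.085 to 0.435 between control and 0.284 to 0.564 between knockout libraries. With the GC and length trend removed, 1463 genes passed, 595 higher and 868 lower, so that the share of higher genes went from 56.8% to 40.7%. Of these 1463 genes, 53 changed at least 2-fold, 927 were called in the same direction in both analyses and 7 in opposite directions. Libraries of the same group also differed in their weight on the count: without knockout replicate 1 or 2, or control replicate 3, 2151, 2513 or 3162 genes passed. With that trend removed the count was 3589, 716 and 882 without control replicate 1, 2 or 3, and 363, 416 and 607 without knockout replicate 1, 2 or 3. Control replicate 1 stood apart on the second principal component, at 34.9 against -15.1 to -2.03 for the others. The groups did not overlap in 6767 of the tested genes (46.3%), against 10% by chance.

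**Figure D1:**
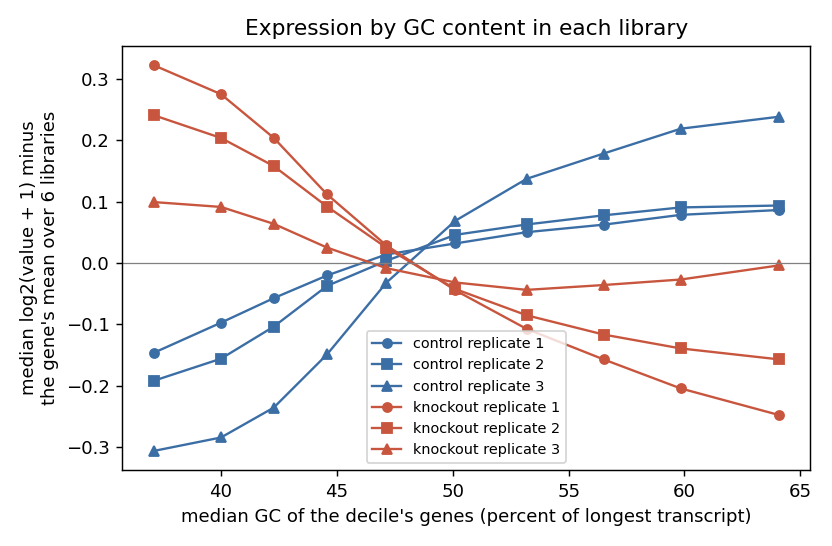
Median log2(value + 1) of the genes in each decile of GC content, as the deviation from each gene's mean over the 6 libraries (vertical axis), against the decile's median GC percent (horizontal axis), with a line per library and control in blue, knockout in red. In the lowest decile the control libraries lie between -0.307 and -0.147 and the knockout libraries between 0.099 and 0.323.

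The largest increases included GJA1, which encodes the gap junction protein connexin 43, from 51.2 ± 30.4 to 148 ± 23.7 normalized counts (n = 3 each; log2 fold change 1.65, SE 0.31, limma adjusted p = 0.00079). GRAMD1B, a sterol transfer protein, rose from 75.8 ± 15.7 to 233 ± 28.2 (1.62, SE 0.20, adjusted p = 4.6e-05), and MMP8, a neutrophil collagenase, from 36.7 ± 12.3 to 97.4 ± 9.98 (1.43, SE 0.28, adjusted p = 0.0012). ZNF385B (1.41), BCHE, which encodes butyrylcholinesterase (1.32), and INAVA (from 42.0 to 99.2 counts) also rose with the trend present and with it removed. WDR17 (1.44), NLGN1 (1.36), RNF180 (1.28) and the microRNA host gene MIR17HG (1.28) rose as deposited and stood at 1.01, 0.89, 0.85 and 0.87 with the trend removed (adjusted p = 0.052, 0.13, 0.12 and 0.059). Among the largest decreases, COL1A2, a chain of type I collagen (chromosome 7, 94394561 to 94431232), fell from 705 ± 35.8 to 272 ± 41.6 (-1.38, SE 0.13, adjusted p = 1.4e-05), and by more with the trend removed (-1.70, SE 0.14, adjusted p = 0.00045). PI16, a peptidase inhibitor, fell from 133 ± 47.8 to 49.0 ± 13.7 (-1.40, SE 0.28, adjusted p = 0.0014), and the Hedgehog transcription factor GLI2 from 484 ± 139 to 221 ± 33.1 (-1.10, SE 0.18, adjusted p = 0.00035). HTR1D, a serotonin receptor (from 100 to 39.6 counts), LZTS1 (-1.25), PCBP3 (-1.21), FAM167A (-1.18), the BMP-binding protein BMPER (-1.18) and CALHM3 (-1.14) were lower in both analyses. P2RY6, a nucleotide receptor, was lower as deposited (-1.16) and stood at -0.96 (SE 0.31, adjusted p = 0.078) with the trend removed.

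**Figure D2:**
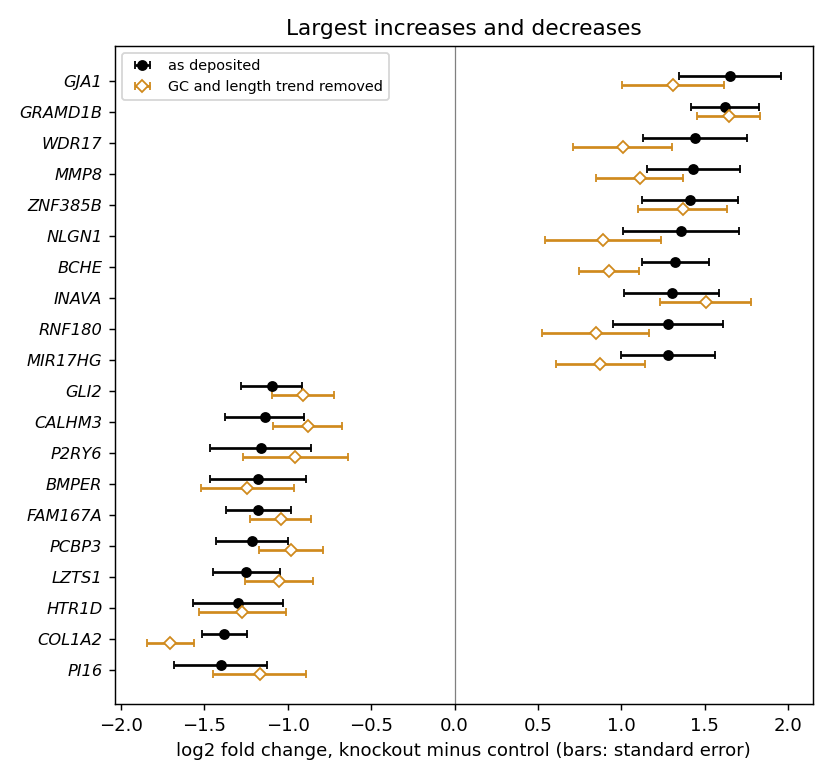
Log2 fold change (horizontal axis, knockout minus control, bars show the SE) of the 10 genes with the largest increases and the 10 with the largest decreases, as deposited (filled circles) and with the GC and length trend removed (open diamonds). COL1A2 moves from -1.38 to -1.70 with the trend removed, and NLGN1 from 1.36 to 0.89.

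Markers of epithelial and mesenchymal cells went both ways. EHF, an epithelial transcription factor, rose from 1440 ± 137 to 2171 ± 189 normalized counts (n = 3 each; 0.59, SE 0.10, limma adjusted p = 0.00041), and DSP, the desmosomal plaque protein desmoplakin, from 4607 ± 354 to 6169 ± 258 (0.42, SE 0.083, adjusted p = 0.0013). CLDN4, a tight junction claudin (-0.36, SE 0.082, adjusted p = 0.0035), and JUP, plakoglobin (-0.42, SE 0.11, adjusted p = 0.011), were lower, although neither passed with the trend removed (adjusted p = 0.06 and 0.2). On the mesenchymal side, ZEB1, a repressor of epithelial genes, rose from 1240 ± 66.7 to 2135 ± 127 (0.78, SE 0.094, adjusted p = 3.8e-05) and CALD1, caldesmon, from 5708 ± 362 to 9082 ± 663 (0.67, SE 0.083, adjusted p = 4.6e-05), while COL6A2 fell from 2880 ± 271 to 1678 ± 95.8 (-0.78, SE 0.094, adjusted p = 4.5e-05). Of 36 measured epithelial markers 5 were higher and 8 lower, and of 33 mesenchymal markers 4 were higher and 9 lower, the same numbers when adjusted over the list alone. The median log2 fold change was -0.021 for the epithelial and -0.16 for the mesenchymal markers, a difference of 0.139 (two-sided permutation p = 0.184). Fry called the mesenchymal list lower (adjusted p = 0.038, and 0.0047 with the trend removed), whereas camera did not call it (adjusted p = 0.128 and 0.104). With the trend removed, which turned the epithelial median to 0.086, the epithelial counts were 4 higher and 0 lower and the mesenchymal counts 3 and 6. The mesenchymal median was then -0.098 and the difference 0.185 (permutation p = 0.0071). ZEB1, CALD1, EHF and DSP stayed higher with the trend removed, by 0.36, 0.36, 0.33 and 0.36 (adjusted p = 0.0048, 0.0045, 0.015 and 0.0038).

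**Figure D3:**
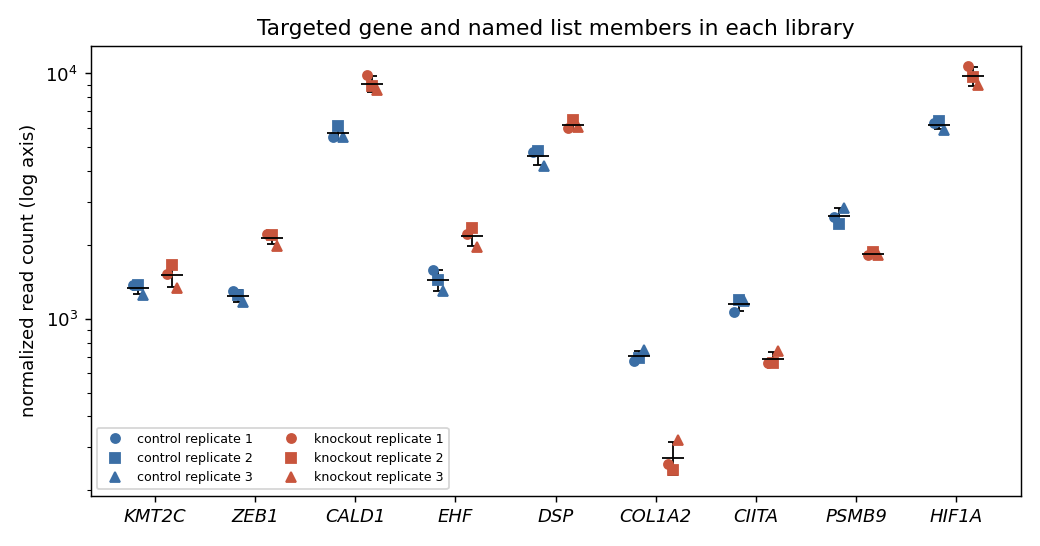
Normalized read counts (vertical log axis) of KMT2C and 8 named list members in each library, with control in blue and knockout in red, symbols for replicates, and black bars for the mean ± SD of n = 3. KMT2C overlaps between the groups (1255 to 1379 against 1339 to 1660), and COL1A2, CIITA and PSMB9 lie lower in every knockout library.

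Basal keratins and hybrid state markers fell as a list (median -0.14; camera adjusted p = 0.047), with 2 of 27 members higher and 7 lower, the same adjusted over the list alone. That call was lost to an adjusted p = 0.632 with an estimated correlation, and camera gave 0.095 with the trend removed. It was also lost, among other settings, without control replicate 2 (0.067) or knockout replicate 3 (0.054), after quantile normalization (0.11) and without the filter on low values (0.061). ITGB4, the hemidesmosome integrin, fell by 0.52 (SE 0.089, limma adjusted p = 0.0004). ITGA2, the collagen-binding alpha-2 integrin, rose from 2247 ± 186 to 3777 ± 387 (0.75, SE 0.096, adjusted p = 5.5e-05). Both genes also passed with the trend removed, at -0.32 and 0.35, unlike ITGA6 (0.31 as deposited, 0.046 with the trend removed).

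Collagens, laminins and matrix glycoproteins fell as a list (median -0.15; camera adjusted p = 0.022, and adjusted p = 0.632 with an estimated correlation), with 4 of 42 members higher and 14 lower, the same adjusted over the list alone. Camera gave an adjusted p of 0.13 with the trend removed and 0.088 after quantile normalization, which left the median at -0.16. With the trend removed, 2 members were higher and 6 lower, or 4 and 7 adjusted over the list alone. Fibroblast and endothelial genes also fell (median -0.33, camera adjusted p = 0.0052, and adjusted p = 0.632 with an estimated correlation). That list shares collagens, COL1A2 among them, with the matrix list, and its fibroblast genes with the mesenchymal list. Fibroblasts as a source of the matrix genes were not tested, and the labels name cells of the MDA-MB-231 line alone. Besides COL1A2 and COL6A2, the members named by rule were EFEMP1, fibulin-3, which rose by 0.58 (SE 0.080, limma adjusted p = 8.8e-05), and COL4A3, which rose by 1.72 from a low level of 11.8 ± 7.50 (SE 0.49, adjusted p = 0.013) and stood at 1.71 (SE 0.50, adjusted p = 0.054) with the trend removed. Of 31 proteases and inhibitors, 8 were higher and 9 lower (9 and 13 adjusted over the list alone), among them the membrane sheddases ADAM9 and ADAM10, each higher by 0.65 (SE 0.077, adjusted p = 3.8e-05), and ADAM19, lower by a log2 change of -0.49 (SE 0.092, adjusted p = 0.00089). With the trend removed ADAM9, ADAM10 and ADAM19 stood at 0.27, 0.19 and -0.38 and still passed. The proteases counted 7 higher and 2 lower with the trend removed, and their median turned from -0.16 to 0.019. Of 30 integrins and adhesion receptors 7 were higher and 5 lower, of 36 TGF-beta responsive genes 1 was higher and 6 lower, and of 34 WNT and NOTCH genes 2 were higher and 7 lower. Camera called none of these lists (adjusted p = 0.718, 0.174 and 0.076), nor the proteases (0.718). Trend removal left 1 higher and 2 lower among the integrins, 2 and 2 among the TGF-beta responsive genes and 1 and 4 among the WNT and NOTCH genes. TIMP3, an inhibitor of matrix metalloproteases, fell by 0.48 (SE 0.099, adjusted p = 0.0016), and stood at -0.48 with the trend removed (adjusted p = 0.01). TGFBR1, a TGF-beta receptor, was higher by 0.30 (adjusted p = 0.029) as deposited and stood at -0.12 (adjusted p = 0.25) with the trend removed. FZD7 and FZD1, which encode WNT receptors, fell by 0.63 and 0.46 and passed in both analyses.

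Genes of MHC antigen presentation fell as a list (median -0.34; camera adjusted p = 0.00011, and adjusted p = 0.632 with an estimated correlation), with 1 of 30 members higher and 15 lower, or 1 and 18 adjusted over the list alone. Leukocyte genes fell beside it (median -0.35; camera adjusted p = 0.047, and adjusted p = 0.632 with an estimated correlation). CIITA, the transactivator of MHC class II genes, fell from 1150 ± 69.0 to 686 ± 48.5 normalized counts (n = 3 each; -0.74, SE 0.11, limma adjusted p = 0.0001), and PSMB9, an immunoproteasome subunit, from 2623 ± 208 to 1833 ± 27.0 (-0.51, SE 0.090, adjusted p = 0.00052). ERAP2, a peptide-trimming enzyme, was higher by 0.59 (SE 0.14, adjusted p = 0.0043) and did not pass with the trend removed (adjusted p = 0.265). Trend removal left 0 members higher and 8 lower, 6 of them called lower in both analyses, and the list median was -0.17 (camera adjusted p = 0.00015, and adjusted p = 0.566 with an estimated correlation). HLA genes share sequence with their relatives and are uncertain in gene counts. In the interferon-gamma list, 7 of 44 members were higher and 15 lower, the same adjusted over the list alone. This list shares members with the antigen presentation list, CIITA and PSMB9 among them. Its lower members are therefore in part the same genes. CD274, which encodes the checkpoint ligand PD-L1, rose from 984 ± 126 to 1652 ± 85.3 (0.75, SE 0.11, adjusted p = 0.0001). Once the trend was removed CD274 stood alone as higher (0.42, adjusted p = 0.019) against 10 lower. Of 48 interferon-stimulated genes 7 were higher and 12 lower (9 and 12 adjusted over the list alone), with the RNA sensor DDX58 up by 0.83 (SE 0.096, adjusted p = 3.8e-05), and of 39 NF-kappaB and cytokine genes 2 were higher and 7 lower (2 and 5). Trend removal left 1 higher and 1 lower among the interferon-stimulated genes, whose median turned from 0.018 to -0.11, and 1 and 0 among the NF-kappaB genes, and DDX58 stood at 0.48. Camera called neither of these nor the interferon-gamma list (adjusted p = 0.718, 0.207 and 0.128).

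The genes of hypoxia and glycolysis had 12 of 42 members higher and 1 lower, the same adjusted over the list alone, with a median of 0.075 (camera adjusted p = 0.128). Camera called the list higher after quantile normalization (adjusted p = 0.0073) and without control replicate 3 (0.022) or knockout replicate 1 (0.047). After trend removal 11 were higher and 0 lower, 6 of them called higher in both analyses, and the list rose (median 0.13; camera adjusted p = 7.3e-05, and adjusted p = 0.429 with an estimated correlation). HIF1A, the oxygen-regulated transcription factor, rose from 6187 ± 258 to 9750 ± 883 normalized counts (0.65, SE 0.083, limma adjusted p = 5.3e-05), and the collagen lysyl hydroxylase PLOD2 from 2864 ± 244 to 4649 ± 418 (0.70, SE 0.092, adjusted p = 6.2e-05). They remained higher by 0.23 and 0.27 with the trend removed (adjusted p = 0.013 and 0.035).

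Ribosomal protein genes fell as a list (median -0.17; camera adjusted p = 1.9e-06, and adjusted p = 0.632 with an estimated correlation). None of the 56 members was higher and 22 were lower, or 0 and 24 adjusted over the list alone. RPL10 fell from 33700 ± 1374 to 27299 ± 560 (-0.30, SE 0.075, limma adjusted p = 0.0058) and RPL13 from 77654 ± 3706 to 63303 ± 1172 (-0.29, SE 0.077, adjusted p = 0.0086). Nuclear genes of oxidative phosphorylation fell too (median -0.13; camera adjusted p = 0.0094, and adjusted p = 0.632 with an estimated correlation), 0 of 41 higher and 9 lower, the same adjusted over the list alone, among them CYC1 (-0.34, SE 0.078, adjusted p = 0.004) and NDUFV1 (-0.30, SE 0.075, adjusted p = 0.0065). RPL13, CYC1 and NDUFV1 lost their calls with the trend removed (-0.13, -0.076 and -0.073, adjusted p = 0.178, 0.428 and 0.441), and RPL10 kept its call at -0.18 (adjusted p = 0.044). Once the trend was removed, 21 ribosomal protein genes and 13 of oxidative phosphorylation were lower, of which 5 and 2 were called lower in both analyses, with camera adjusted p = 8.3e-08 and 7.3e-05 (adjusted p = 0.479 and 0.429 with an estimated correlation). Quantile normalization ended both calls (camera adjusted p = 0.11 and 0.088), with medians of -0.061 and -0.11, and the call for oxidative phosphorylation was also lost without knockout replicate 3 (0.075) and with length alone removed (0.076). Many ribosomal protein genes have processed pseudogenes that share their reads. Of 13 mitochondrially encoded genes 3 were higher and 0 lower as deposited, and 0 and 1 with the trend removed.

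Of 43 genes of the cell cycle 7 were higher and 14 lower, of 25 p53 targets 2 and 4, of 36 immediate-early genes 4 and 3, of 34 genes of the amino acid and unfolded protein responses 4 and 2, and of 31 genes of cholesterol and fatty acid synthesis 7 and 4. CENPF, a kinetochore protein, rose by 0.83 (SE 0.12, limma adjusted p = 9.8e-05) and CDT1, a replication licensing factor, fell by 0.49 (SE 0.099, adjusted p = 0.0014), and both passed with the trend removed, at 0.44 and -0.26. Trend removal left 1 higher and 4 lower in the cell cycle, 0 and 2 among p53 targets, and 1 and 0 in each of the other lists named here. Camera called none of these lists (adjusted p from 0.284 to 0.967). Adjusted over the list alone, the counts of 17 of the 26 lists as deposited, and of 6 with the trend removed, were the same as over all genes. With the trend removed they became 5 and 1 for the epithelial, 3 and 8 for the mesenchymal and 15 and 0 for the hypoxia list. As deposited, the others not yet given were 1 and 5 for TGF-beta responsive genes and 3 and 3 for immediate-early genes. In the interferon-stimulated and luminal lists the median lay above 0 while camera pointed down, and in the epithelial, protease, p53 and immediate-early lists the median lay below 0 and the mean above it.

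Markers of other cell types could be tested only in part: 19 of 25 leukocyte, 9 of 20 fibroblast and endothelial, 14 of 24 luminal and 4 of 15 embryonic kidney genes. Every listed gene had reads in each library, so reads of these markers are no sign of such cells. Leukocyte genes fell as a list (median -0.35; camera adjusted p = 0.047, and adjusted p = 0.632 with an estimated correlation), with 1 of 19 members higher and 4 lower. RAC2 (-0.29) and CD14 (-0.69) were lower as deposited but not with the trend removed (adjusted p = 0.644 and 0.279), and CD14 in control replicate 1 (194 counts) lay below all 3 knockout libraries (197 to 222). In contrast, LCP1, an actin-bundling protein, rose from 2473 ± 83.6 to 3201 ± 213 (0.37, SE 0.086, limma adjusted p = 0.0041). The list was not called after trend removal (camera adjusted p = 0.13), after quantile normalization (0.053), over genes with a mean of at least 50 (0.083) or without knockout replicate 2 (0.083) or 3 (0.069). Fibroblast and endothelial genes fell (median -0.33; camera adjusted p = 0.0052, and adjusted p = 0.632 with an estimated correlation), 0 of 9 higher and 5 lower (0 and 6 adjusted over the list alone), among them COL1A2 and PDGFRB (-0.48, and adjusted p = 0.091 with the trend removed). Camera kept that call with the trend removed (median -0.13, adjusted p = 0.026, and adjusted p = 0.429 with an estimated correlation), while limma then called 0 members higher and 2 lower. Luminal breast genes had 1 of 14 higher and 2 lower, and genes typical of an embryonic kidney line 0 of 4 higher and 1 lower (camera adjusted p = 0.76 and 0.354).

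In all, camera at the preset correlation called 7 of 26 lists as deposited, each of them lower, and 5 with the trend removed, with 4 lists called in both. With an estimated correlation camera called 0 lists in either analysis, with 0 and 1 lists at an unadjusted p under 0.05. That setting also has few degrees of freedom, so correlation need not be the reason. With the trend removed the fibroblast and endothelial list lost its call at an estimated correlation of -0.015, below the preset 0.01. Fry called 2 and 9 lists, all of them lower. As deposited these were the mesenchymal and the fibroblast and endothelial lists (fry adjusted p = 0.038 and 0.045). After trend removal they were these 2, the H3K4 methyltransferase complexes, basal and hybrid markers, matrix genes, oxidative phosphorylation, ribosomal proteins, WNT and NOTCH genes and embryonic kidney genes. The fibroblast genes of the fibroblast and endothelial list, COL1A2 and PDGFRB among them, are also mesenchymal markers. The calls on the mesenchymal and the fibroblast and endothelial lists are therefore not independent.

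**Figure D4:**
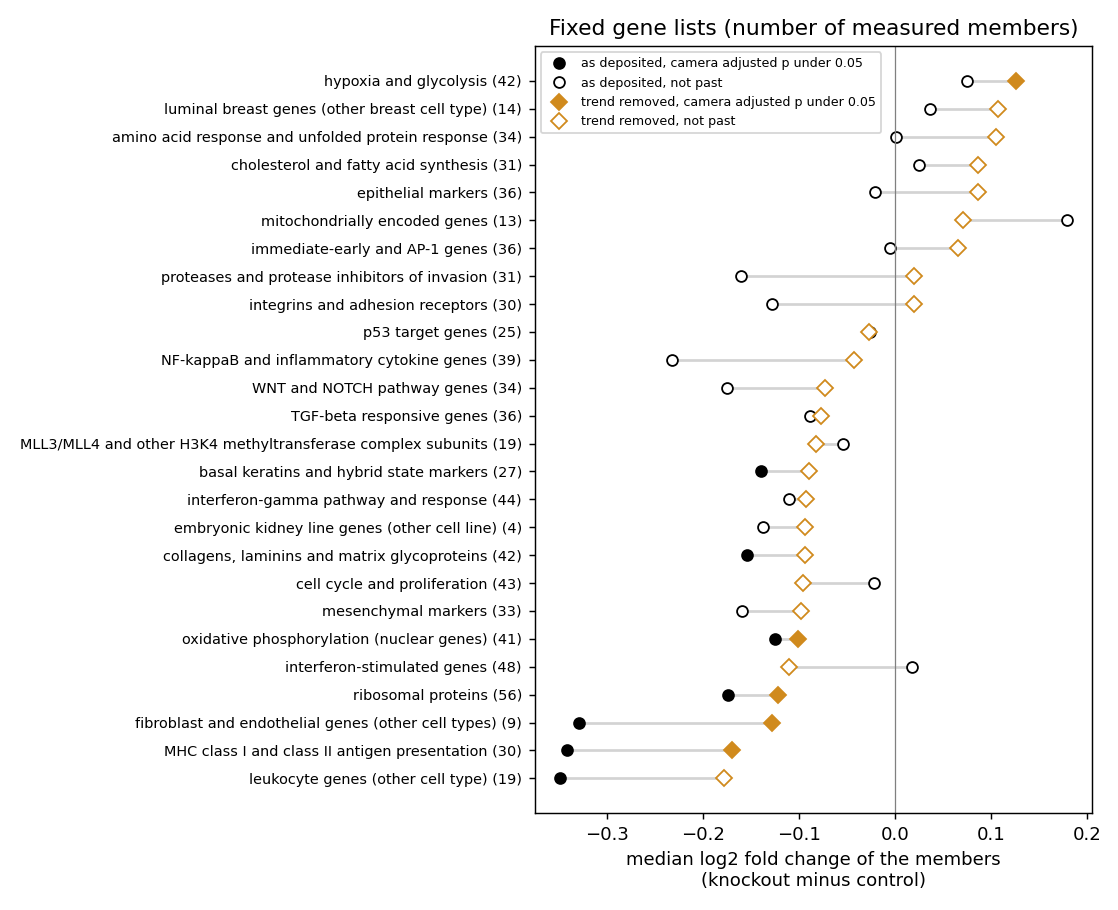
Median log2 fold change (horizontal axis, knockout minus control) of the measured members of each of the 26 gene lists, as deposited (black circles) and with the GC and length trend removed (orange diamonds), filled where camera at the preset correlation gave an adjusted p under 0.05. The median of the antigen presentation list is -0.34 as deposited and -0.17 with the trend removed, and that of the epithelial list goes from -0.021 to 0.086.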

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

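The trend removals and the count tests on recovered reads were chosen after the data were seen. Of 14618 genes, 4859 changed in the main analysis (2760 higher, 2099 lower). Leaving out each library in turn gave 2151 to 6167 changed genes, 1591 to 3301 higher and 560 to 2866 lower, lowest without knockout replicate 1 and highest without control replicate 1. Without control replicate 3 and knockout replicate 2, 3162 and 2513 changed. The higher genes fell to 1591 and 1794 without knockout replicates 1 and 2, and the lower genes to 1350, 1071, 560 and 719 without control replicates 2 and 3 and knockout replicates 1 and 2. Fewer samples lower the power, but why the libraries weigh so unequally was not tested. Removing the GC and length trend left 1463 (595 higher, 868 lower), 10 spline terms 1461 (594 and 867), and GC alone 1400 (617 and 783). The share of higher genes among the changed went from 56.8% to 40.7%, 40.7% and 44.1% under these, and to 45.6% with length alone removed. The count of 1463 ranged from 363 to 3589 when each library was left out, again lowest without knockout replicate 1 and highest without control replicate 1. It was 716, 882, 416 and 607 without control replicate 2, control replicate 3, knockout replicate 2 and knockout replicate 3. An adjusted p under 0.01 left 2320 (1707 and 613), and a 2-fold minimum 147 (109 and 38), by construction. edgeR called 4904 genes and DESeq2 5243.

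The labels do not say whether the replicate numbers pair the libraries, and the values did not settle it. The correlations of same-numbered deviations from the group means were small, at 0.066, 0.0063 and 0.13. With the replicate number as a block, 6265 genes passed (3241 higher, 3024 lower), and 1313 with the trend removed. The block ended the camera calls of the basal and hybrid markers (adjusted p = 0.066) and the leukocyte genes (0.073). Knockout replicates 1 and 2 both deviated most like control replicate 1, and knockout replicate 3 like control replicate 3.

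KMT2C did not pass under any alternative run. Its log2 fold change turned from 0.17 to -0.039 with the GC and length trend removed, -0.046 with 10 terms and -0.10 with length alone. With GC alone removed it stayed positive, at 0.042, so it turned only where length was removed. The cause was not tested further. The difference between epithelial and mesenchymal medians kept its sign and passed with the trend removed (0.185, 0.186 with 10 terms and 0.208 with GC alone, permutation p = 0.0071, 0.0085 and 0.002). As deposited, the difference of 0.139 ranged from 0.045 to 0.203 without each library, and none of these passed (permutation p from 0.099 to 0.73). The 7 lists called by camera became 4 to 12 without each library (4 without knockout replicate 3, 11 without control replicate 1, 12 without control replicate 3), 4 after quantile normalization, 3 at a preset correlation of 0.05, 4 on fold changes, 0 with an estimated correlation and 0 with that and the trend removed. The setting with an estimated correlation also has far fewer degrees of freedom. The cause was not tested otherwise. The epithelial list, down at an adjusted p of 0.728, pointed up with the trend removed (0.0511, 0.0582 with 10 terms, 0.0474 with GC alone and 0.489 with an estimated correlation), and ranged from 0.213 to 0.987 without each library, pointing up without control replicate 3 (0.889) and knockout replicate 1 (0.987). The named genes TGFBR1, BIRC3 and ZMAT3 turned with the GC and length trend removed, with 10 terms and, for the first pair, with GC alone: TGFBR1 (-0.124, -0.137 and -0.105), BIRC3 (-0.019, -0.0089 and -0.017) and ZMAT3 (-0.027 and -0.029). Of 100 named genes other than KMT2C, 46 kept their call with the trend removed, 51 lost it and 3 turned, against 92 kept and 8 lost with length alone removed and 75 and 25 without knockout replicate 1. With a mean of at least 10 in place of 50, 0 of the 20 largest changes stayed among the largest. Alternatives planned for raw counts, or for a table with the authors' comparison alone, did not apply and were not run.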

Other observations

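The tests of transcript length, of the knockout as the source of the GC trend, of a fall in KMT2C under that trend, of shared sequence and of the trend behind the antigen presentation list were chosen after the results were seen, as were PTPRC, ARHGDIB, the genes named in the next paragraph and the regions of chromosomes.

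With the GC and length trend removed, the rule for named genes gave further genes that had not been among the largest changes. DAPK1, a death-associated kinase, was higher by 1.08 (SE 0.11, limma adjusted p = 0.00072) and LGALS12, a galectin, by 1.05 (SE 0.12, adjusted p = 0.0011), from 212 and 230 normalized counts to 423 and 424. FER1L4, a pseudogene whose reads may be shared with relatives, DMKN and NPM2 were higher by 1.42, 1.10 and 1.11. The axon guidance ligand SLIT2 was lower by -1.08 (SE 0.11, adjusted p = 0.00072) and FLRT2, an adhesion protein that binds UNC5 guidance receptors, by -1.29 (SE 0.19, adjusted p = 0.0022). FLRT2 stood at -0.77 as deposited, and its longest transcript has 33679 bases. Part of its value thus comes from the trend fitted at its GC content and length. ATP9A and the interferon-induced GTPase GBP4 were lower as well (-1.04 and -1.03). All of these had the same direction as deposited.

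Genes on the second side of chromosome 16, past its centromere (46580554 to 90047773), had the lowest median among 43 chromosome regions after trend removal, at -0.11 over 302 genes, with 73.2% of them below 0, 37 called lower and 3 higher by limma. The first side of this chromosome had a median of -0.063 over 353 genes, the lowest but 4. On the second side the median deviation was 0.050, 0.060 and 0.059 in the control libraries and -0.058, -0.044 and -0.051 in the knockout libraries. Shifts were not confined to chromosome 16. The medians were -0.074 on the second side of chromosome 15 and -0.072 on the first side of chromosome 14. The first side of chromosome 18 had the highest median of the 43 regions, 0.075 over 53 genes, with 34.0% of them below 0.

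The first pattern weighed was the GC trend, with GC-poor transcripts higher in the knockout libraries. Transcript length does not account for it, since the partial rho with GC content at fixed length was -0.651. A bias between library preparations stays open: libraries of the same genotype also differed along GC, with absolute rhos up to 0.435 between control and 0.564 between knockout libraries, and the trend among 1533 non-coding genes and pseudogenes (rho -0.297) fell just short of the -0.3 set for it. The rhos of the groups, centred on all 6 libraries, did not overlap (0.475 ± 0.167 and -0.502 ± 0.233, mean ± SD, exact permutation p = 0.1, the lowest possible). The knockout itself stays open as a source, since the labels give no preparation batch that would tell it from a bias that follows the groups.

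The second pattern was a KMT2C transcript that was not lower in the knockout libraries. A fall hidden by the trend is argued against by the value after its removal, -0.039 (SE 0.071). Reads of other genes are argued against by the 6.98% of 50-base words of the transcript that occur in transcripts of other genes. A library placed by itself in the wrong group is argued against by the 6 of 6 libraries that correlated better with their own group than with the other after trend removal, which cannot speak to an exchange of all labels. A cut that spares the transcript level, or incomplete editing, stays open and was not tested.

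The third pattern was the lower expression of antigen presentation genes. Whether the GC and length trend is the whole cause of this pattern was not settled. After removal the list median went from -0.34 to -0.17, with 0 members higher and 8 lower in limma. Camera at the preset correlation still called the list (adjusted p = 0.00015). With the trend removed it also called lists in every split of the libraries. The mixed splits keep part of the group difference, and their counts do not say which lists were called. They therefore cannot weigh on the antigen presentation list. Fry did not call this list (adjusted p = 0.118), nor did camera with an estimated correlation (adjusted p = 0.566), a setting with few degrees of freedom. The labels name cells of the MDA-MB-231 line alone and no leukocytes. The values by themselves leave leukocytes in the control libraries open, since the leukocyte list had a median of -0.18 and a camera adjusted p of 0.129 after removal. Its most abundant members were RAC2 (13364 and 10935 normalized counts in control and knockout), ARHGDIB (4124 and 3808) and LCP1 (2473 and 3201), and of these LCP1 was higher in the knockout libraries, whereas PTPRC, the leukocyte antigen CD45, was lower with the trend removed (-0.76, limma adjusted p = 0.013). An effect of the knockout is untested beyond the comparison itself.

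The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes control and knockout libraries. A difference between the groups, whatever its source, then adds to the spread and lowers the gene count, so these gene counts give no baseline for chance. Of the 10 splits, 1, the real one, gave as many as 4859 changed genes, and the highest other gave 0 in limma, with up to 1501 genes at an unadjusted p under 0.05. With the trend removed, 1 of the 10 gave as many as 1463, and the highest other gave 0, with up to 1029 genes at an unadjusted p under 0.05. For lists called by camera, 7 of the 10 splits gave as many as the real 7, and the highest other gave 14. With the trend removed, 10 of the 10 gave as many as the real 5, and the highest other gave 12. Camera at the preset correlation thus called lists in most arrangements of the libraries, and in all of them with the trend removed, and the cause was not tested. Since the mixed splits keep part of the group difference, the list counts give no baseline for chance either.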
